A study of Mus musculus with 8 samples.

How the data were processed

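Total RNA from the left and the right heart ventricle of adult male C57Bl/6j mice, a standard inbred laboratory strain, was measured on 2-colour Agilent microarrays. Per the labels' protocols, ventricles were dissected and minced, RNA was purified on columns, amplified with T7 RNA polymerase and labelled with either Cy3 or Cy5. The 8 samples (4 per side) were hybridised on 4 arrays of 1 slide. Each array carried 1 Cy3 and 1 Cy5 sample of the same side, so the arrays gave 8 single-channel profiles and no direct left-against-right ratio. On both sides, replicates 1 and 3 were labelled with Cy3 and replicates 2 and 4 with Cy5. Replicates 1 and 2 shared an array, as did replicates 3 and 4. Groups were taken from the sample titles.

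The values used are log2 values as the authors deposited them, 1 column per sample. Images were read with Agilent Feature Extraction, per the submitters' processing notes; its version, the background correction and the rule that set spots to null are not given in the sources used here. The deposited log2 columns each have a median of 0. In every sample, 2 raised to the deposited value and multiplied by 1 constant gave whole numbers for 100% of the spots (tolerance 0.01), so each value is the log2 of a whole-number brightness over the median brightness of that sample's own spots. The implied median brightness was 154 to 191 scanner units in the Cy3 samples and 432.5 to 556.5 in the Cy5 samples. The median was taken over different spots in each sample: of 44397 rows, 1454 to 1496 were null in a Cy3 sample and 15067 to 17737 in a Cy5 sample. Over the 24017 spots with a value in all 8 samples, the sample medians spanned 0.14 on the log2 scale within Cy3 and 0.46 within Cy5. A spot is called a feature below. The number of arrays, not a count of molecules, limits the precision of these values.

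Rows are identified by the feature's number on the array. Those numbers are not paired with gene names in the material used here, so features are given by number, no genomic position or annotation is given, and the 30 gene lists fixed beforehand (patterning genes, sarcomere, ion channels, metabolism, and markers of atrium, vessel, blood, fat, nerve and other cell types) could not be tested. The spots of a probe could not be averaged and genes could not be formed, so a feature is the unit throughout. Feature numbers run to 45220. Among the 6 divisors of that number from 60 to 120, a width of 85 columns and 532 rows placed null features above one another most often (42.4% of null features had another exactly 1 row on, against 14.1% for the next width), and this grid was used for positions.

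Features with a value in at least 3 samples of each side were tested, which left 27462; another 15558 had some values and were not tested. Left and right were compared with limma 3.58.1 (R 4.3.3, with statmod 1.5.0 for the correlation) on the deposited log2 values: lmFit with side and dye as terms, the shared array as a random block (duplicateCorrelation, consensus correlation 0.206), eBayes, two-sided p-values and Benjamini-Hochberg adjustment at a threshold of 0.05. The dye term of the same model gave the Cy5 minus Cy3 difference. Since the column medians were all 0, no further normalisation was applied. Because each array held 1 side only, array and side can be separated only through the spread between the 2 arrays of a side. The labels call the 4 samples of a side biological replicates and do not say whether left and right samples with the same number came from the same heart. No samples were identical: same-array pairs correlated at 0.98 to 0.99 over features, and at most 0.0208% of values agreed exactly between any samples.

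This design, the alternatives except those said to be added, and the rule for named features were set before the data were examined. The rule took the features with the smallest p in each direction whose left samples lie on one side of all right samples within each dye. It asked for 12 genes per direction. As features carry no gene names, 2 per direction are given by number and the 12 are summarised.

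The alternatives were a replicate block in place of dye, no array block, array means, no dye term, each dye alone, quantile normalisation, centring each sample on its median over the features with a value in all 8 samples, 2 filters on dim features, complete features only, an intensity trend, robust moderation, other thresholds, and leaving out each sample in turn. Leaving out features near surface defects, and a side-by-dye interaction, were added after the data were seen. The model was tested on 3 simulated data sets with 200 seeded changes each. They had the real levels, dye differences and array correlation of the 27462 features, with the model's moderated variances as spread. It called 2.67% of the seeded 1.5-fold changes, 27.3% of the 2-fold, 94% of the 4-fold and 97.3% of the 8-fold changes, and 0.0379% of unchanged features. The simulation used normal noise and held no surface defects. Benjamini-Hochberg adjustment is less strict when many true changes are present. With fewer true changes than the 200 seeded, the share called would be lower, so these rates may overstate the power of the real test.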

Results

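Gene expression was profiled in left and right heart ventricles of adult male mice, 4 samples per side, to find transcripts whose level differs between the sides. The 4 arrays gave values for 42901 to 42943 features in the Cy3 samples. The Cy5 samples had 26660 to 29330 features with a value. Levels below are log2 values relative to the sample's own median, and differences are left minus right.

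No feature passed the test for a difference between left and right ventricles, which does not show that the sides are equal. Over the 24017 features measured in all 8 samples, the mean left and mean right levels correlated at 0.989 across features, which are not independent replicates. Single samples correlated at 0.96 to 0.99 whatever their side and dye, so this value says little about side. The estimated difference was under 1.5-fold for 25267 of the 27462 tested features (92.0%). An estimate of at least 2-fold was found for 925 features, 474 higher in left and 451 higher in right. The 95% interval of the difference excluded a 2-fold change in either direction for 22254 features (81.0%), and a 1.5-fold change for 9374 (34.1%). Side varies only between 4 arrays, and the intervals use 1 within-array correlation of 0.206 for all features. They may therefore be too narrow, and these shares too high.

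In limma's moderated test with side, dye and a random array block, 0 of the 27462 features had an adjusted p under 0.05 (n = 4 per side), and 0 had one under 0.10. The smallest adjusted p was 0.91. An unadjusted p under 0.05 was found for 1194 features (4.35%), against 1373 that 5% of the tests would give by chance. Of the 1194, 488 were higher in left and 706 higher in right. With each sample centred on the features measured in all 8 samples, the direction of that excess turned, with 668 higher in left and 349 higher in right. The median difference over all features moved from -0.06 to 0.02 with this centring. The excess also turned without left replicate 4 (1174 higher in left, 948 in right) and without right replicate 4 (598 and 480). In the other fits without 1 sample more were higher in right, up to 887 against 333 in left without right replicate 3. Some of the 1194 features were neighbours on the array. Features 64 to 73, side by side in 1 grid row, all had an unadjusted p under 0.05 in this test and were all higher in left. Neighbouring features thus need not be separate observations, and clustering of the 1194 over the whole grid was not tested. Under this test the count of 0 rose when any 1 of the 4 Cy3 samples was left out: to 10 without left replicate 1, 52 without left replicate 3, 31 without right replicate 1 and 25 without right replicate 3. It also rose to 404 when the dye term was left out.

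Samples of opposite sides were about as far apart as samples of the same side. Among Cy3 samples, the SD over features of the difference between 2 samples was 0.53 for the left pair and 0.56 for the right pair, and 0.51 to 0.58 for the 4 left-right pairs. Among Cy5 samples it was 0.73 for the left pair and 0.66 for the right pair, and 0.49 to 0.77 for the 4 left-right pairs. With 2 same-side and 4 opposite-side pairs per dye, sharing samples, no test of this difference was made. Side separated the samples within both dyes for 1856 of the 24017 features measured in all samples (7.73%). Setting the arrays of replicates 1 and 2 against those of replicates 3 and 4, which mixes the sides, separated 8.46% of the features, and the remaining way of pairing the arrays separated 7.13%.

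**Figure D1:**
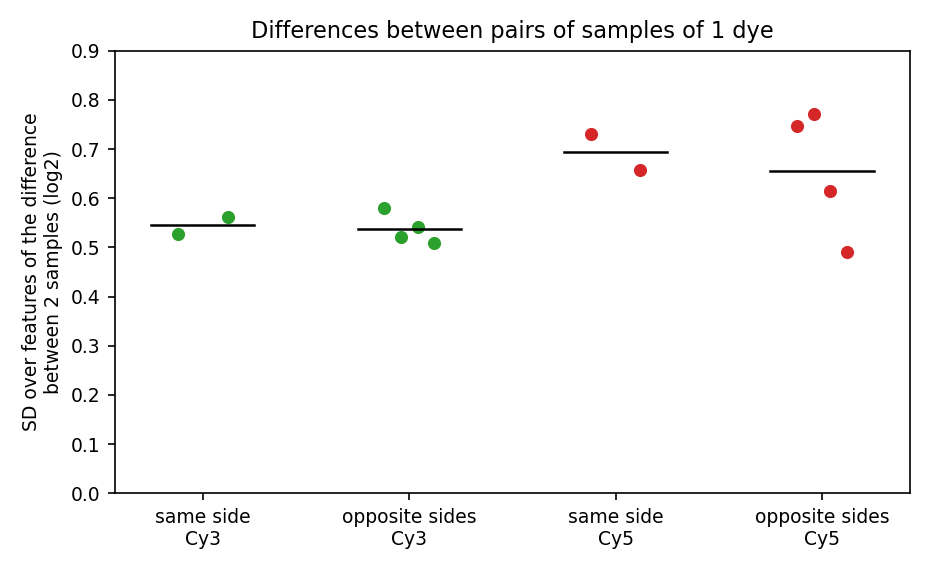
Each point is a pair of samples labelled with the same dye, and its height is the SD over 24017 features of the log2 difference between them; green is Cy3, red is Cy5 and the bars are means of the pairs. The left-right pairs span 0.51 to 0.58 in Cy3 and 0.49 to 0.77 in Cy5, around the values of the same-side pairs.

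Feature 44749 had the smallest p of all features and an estimate 3.24-fold higher in left ventricles. Its level, with Cy5 samples moved to the Cy3 scale, was 7.19 ± 0.27 in left and 5.50 ± 0.23 in right ventricles (SD, n = 4 each), a difference of 1.70 ± 0.21 (SE). Its adjusted p in the limma test was 0.91. It fell to 0.0385 without left replicate 3, 0.0306 without right replicate 1 and 2.69e-05 without the dye term. With array means it was 0.302, and in the other fits without 1 sample it was 0.182 or higher. Feature 42277 had an estimate 5.88-fold higher in left, at 4.29 ± 0.74 against 1.73 ± 0.18 (SD, n = 4 each), a difference of 2.56 ± 0.36 (SE). Its left samples differed among themselves, with 3.41 and 5.02 in the Cy3 samples and 2.93 and 3.75 in the Cy5 samples. Its adjusted p in the limma test was 0.91 too, 4.91e-06 without the dye term and 0.461 with array means.

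Among features with higher estimates in right ventricles whose sides were separated within both dyes, feature 12410 had the smallest p. It stood at -0.21 ± 0.19 in left and 0.75 ± 0.06 in right (SD, n = 4 each), a 1.95-fold difference of -0.96 ± 0.16 (SE). Feature 26112 stood at 0.89 ± 0.26 in left and 2.20 ± 0.22 in right (SD, n = 4 each), a 2.47-fold difference of -1.31 ± 0.22 (SE). The adjusted p of both was 0.91 in the limma test, and without the dye term it was 0.0231 for feature 12410 and 0.000752 for feature 26112. With array means it was 0.67 and 0.296 in the same order. Both features were dim. Feature 12410 dropped out when the lowest 30% of features were left out, and both did when those below the median level were left out. As deposited, the Cy5 values of feature 12410 were -2.23 and -1.92 in left and -1.06 in both right samples. The rule by which these 4 features were chosen fixes their direction within each dye. The differences in Cy3 alone were 1.48, 2.41, -0.90 and -0.94 for features 44749, 42277, 12410 and 26112, and in Cy5 alone 1.91, 2.70, -1.02 and -1.67. Across the 12 features with the smallest p per direction, all had an adjusted p of 0.91 in the limma test. Of the 12, 2 per direction lay within 2 grid steps of a feature that was at least 8-fold brighter on 1 array alone. The estimates of the other 10 ranged from 1.71-fold to 5.88-fold higher in left and from 1.52-fold to 3.10-fold higher in right, and those of the 2 near such features reached 3.48-fold and 6.87-fold.

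**Figure D2:**
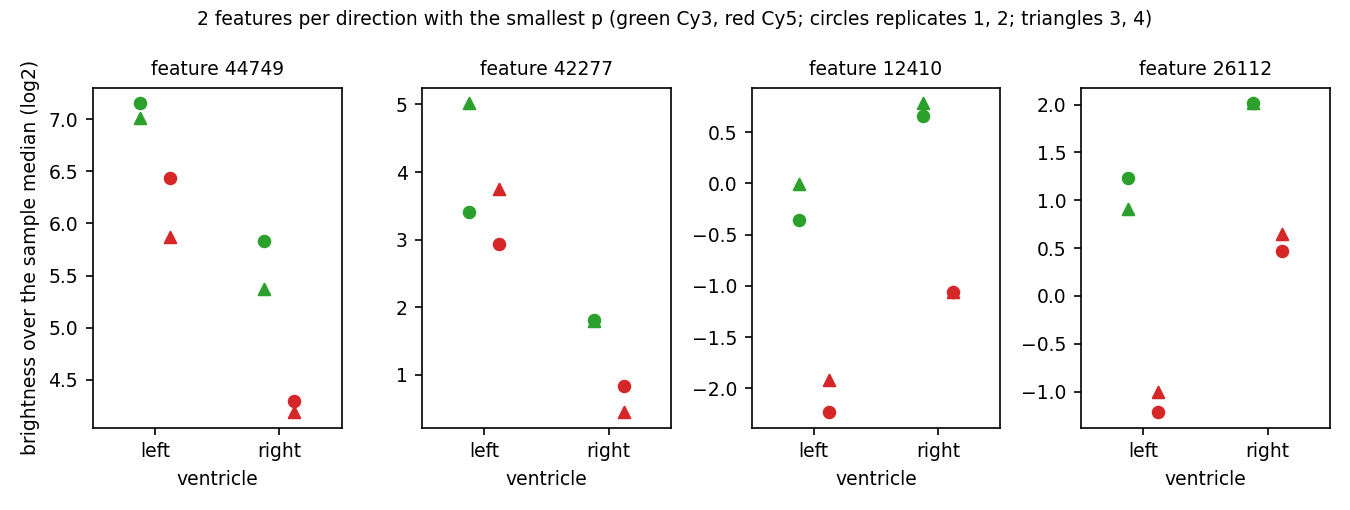
Log2 brightness over the sample median (vertical axes, which differ between panels and do not start at 0) of the 2 features per direction with the smallest p, in left and right ventricles. Each point is a sample, green for Cy3 and red for Cy5, with circles for the array of replicates 1 and 2 and triangles for that of replicates 3 and 4; within each dye the sides do not overlap, and no feature passed adjustment.

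Differences were unevenly spread over the range of brightness. In the brightest 5493 tested features 51 (0.928%) had an estimate of at least 2-fold and the 95% interval excluded a 2-fold change for 86.8%. In the dimmest 5493, with mean levels of -2.02 to -1.06, 31 (0.564%) had such an estimate and the interval excluded a 2-fold change for 87.5%. Whether closeness to the background narrows the differences of these dim features was not tested. In the second and the third dimmest groups of 5492 features, the numbers were 399 (7.27%) and 340 (6.19%), and the intervals excluded a 2-fold change for 72.1% and 75.1%. The groups were formed by mean level over the samples, which includes values raised on 1 array alone. A dim feature raised in this way can fall in a brighter group. Such features made up 375 of the 925 estimates of at least 2-fold, and their spread over the groups was not examined. The uneven spread thus need not follow from brightness itself.

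A part of the large estimates came from features that were bright on 1 array alone. In the Cy3 samples, 748 features were at least 8-fold brighter on 1 array than on each of the other 3: 185 on the array of left replicates 1 and 2, 145 on that of left 3 and 4, 230 on that of right 1 and 2, and 188 on that of right 3 and 4. The Cy5 sample of the same array was also at least 2-fold brighter for 395 of the 396 features where Cy5 values could be compared. On the array grid, 649 of the 748 (86.8%) lay next to another such feature of the same array, against a mean of 3.34% and a highest value of 6.55% in 1000 random draws of positions. They formed 91 groups of 3 or more adjacent features, the largest with 24 features in rows 115 to 125 and columns 22 to 26 of the array of right replicates 3 and 4. They made up 375 of the 925 estimates of at least 2-fold (40.5%). None of the 4 named features was among them or within 2 grid steps of one. With these features left out, or with those within 2 grid steps left out too, 0 features passed an adjusted p of 0.05 in the limma test, and 1284 of 27086 and 1168 of 23225 had an unadjusted p under 0.05.

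**Figure D3:**
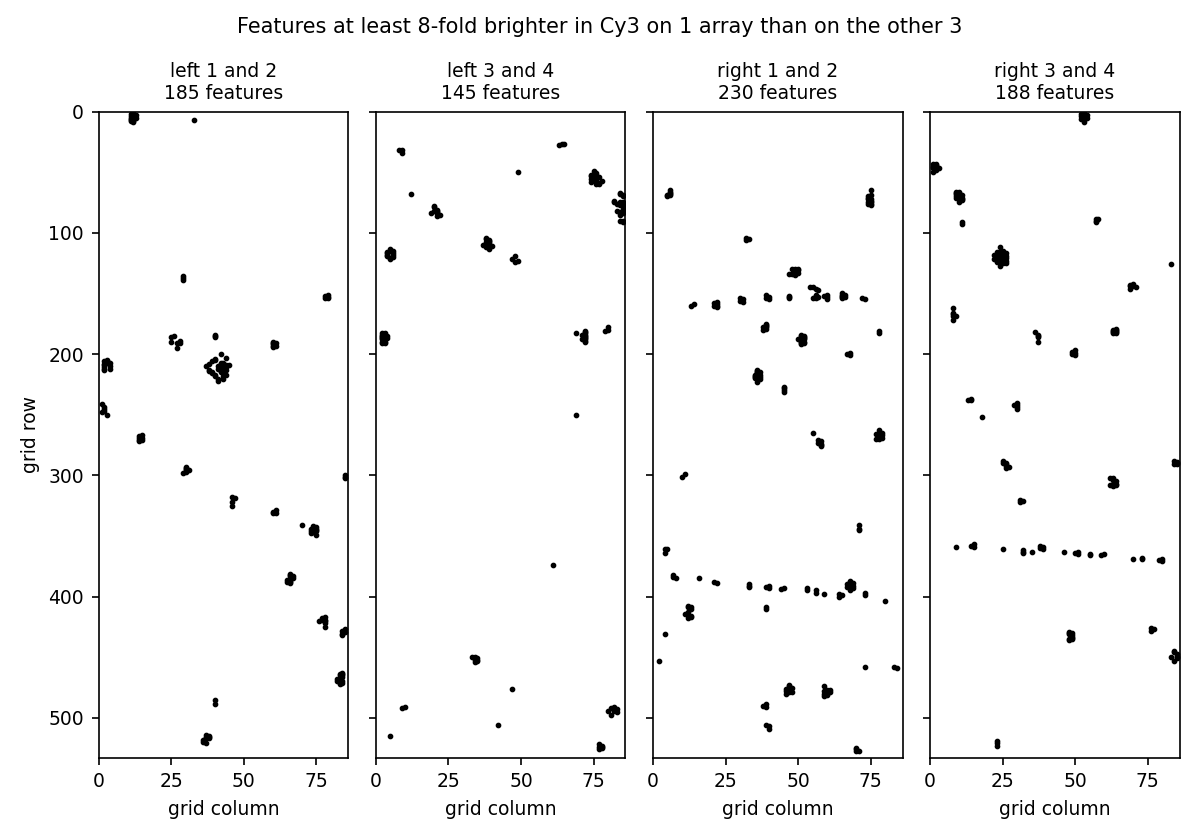
Position on the array grid (column across, row down) of the features at least 8-fold brighter in Cy3 on 1 array than on the other 3, 1 panel per array and 1 dot per feature. The 145 to 230 features per array lie in compact patches, and on the arrays of the right ventricle also in lines that cross the columns.

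Within single dyes, the comparison rested on 2 samples per side. Of 42657 features in the Cy3 samples alone, 0 passed an adjusted p of 0.05 in the limma test and 655 had an unadjusted p under 0.05, 494 of them higher in left. Of 24044 features in the Cy5 samples alone, 0 passed and 469 had an unadjusted p under 0.05, 375 of them higher in right. The median difference was 0.02 in Cy3 and -0.16 in Cy5, and the latter turned to 0.05 with each sample centred on the features measured in all 8 samples. A test of the side-by-dye interaction found 0 of 24017 features with an adjusted p under 0.05 and 202 with an unadjusted p under 0.05.

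As deposited, Cy5 values lay below Cy3 values by a median of -1.68 on the log2 scale, and 26966 of the 27462 features had an adjusted p under 0.05 for dye in the limma test. After quantile normalisation of the 8 samples this count was 0. Each Cy5 sample was centred on its own, smaller set of features. Over the features of each Cy5 sample, the mean Cy3 profile had a median of 1.44 to 1.78. Each Cy3 sample has a median of 0 over its own features. The centring alone would thus give a dye difference of about this size, which need not mean dimmer Cy5 spots.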

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

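The tests in this part were chosen after the values they concern had been seen, except the test of the second pattern, that of surface defects in the third, and the bounds for all tested features there. Each measure was looked at after removing the dye's mean. Of 14 groups of 4 samples looked at, 4 held a sample that stood apart by Dixon's criterion (gap to the nearest sample over the range of the group). The usual chance of about 1 in 20 does not apply to measures that spread more in Cy5 than in Cy3, as the number of features does: it lay within -26.25 to 15.75 of the dye's mean in Cy3 and within -1125 to 1545 in Cy5.

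Right replicate 4 had 29330 features with a value, 1545 above the mean of the Cy5 samples, while the other right samples lay between -83 and 13.75 of their dye's mean (gap over range 0.941). Its median over the features measured in all 8 samples was 0.80, which is 0.26 above the mean of the Cy5 samples, with the other right samples at -0.05 to -0.01 (0.87). Left replicate 2, also Cy5, lay nearly as far below, by -1125 features and -0.20 in the median. Feature 42277 in right replicate 4 lay at -1.54 from its dye's mean, with the other right samples at -1.21 to -1.16 (0.863). Feature 12410 in right replicate 1 lay at 0.39, with the others at 0.51 to 0.52 (0.939).

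The first pattern is the set of 748 features bright on 1 array and on no other. A defect at one place of the array surface, such as a scratch or a particle, would make neighbours bright together and in both dyes, and 86.8% had such a neighbour against at most 6.55% in the random draws. An animal with the same number on both sides is argued against: for features at least 8-fold brighter on 1 array of a side than on the other, the median difference between the same-numbered arrays of the other side was -0.0426 (95% bootstrap interval -0.063 to -0.016). As such features lie in patches on 4 arrays, the interval may be too narrow and does not measure spread between animals. By array, the medians on the other side were -0.138 to 0.114, against 4.08 to 4.67 on the bright side. An animal used for 1 side only is argued against too, as the channels of an array hold different replicates and 99.7% of the comparable features were brighter in both. For the features with no such neighbour the reason stays open.

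The second pattern is the lower level of left Cy5 samples, a median difference of -0.161. The authors' centring on different sets of features may account for it. Centring the mean Cy3 profile in the same way, on the features that each Cy5 sample has, gave a left minus right shift of -0.193. Centred on the features measured in all 8 samples, the Cy5 difference itself was 0.0495, a value that such centring brings near 0 whatever the cause. No biological explanation was tested for it.

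The third pattern is the 404 features called when the dye term is left out. The residual correlation within arrays was then -0.906. The 2 samples of an array carry opposite dyes, so a dye difference that is not fitted lowers this correlation. A negative correlation narrows the standard error of side. Of the 404, 116 (28.7%) were bright on 1 array, as were 1.37% of the tested features. A total of 262 were bright on 1 array or lay within 2 grid steps of such a feature. The other 142 were called again among 590 features when those bright on 1 array or within 2 grid steps were left out. The 142 lie between the bounds set beforehand (135 and 269). As the 262 could not be called again once left out, the upper bound was out of reach, and the result decides nothing. Defects stay open as a source of most of the calls. Differences between arrays that do not follow side may account for the pattern. Pairing the arrays across sides gave 252 and 185 calls on all tested features, between the same bounds. With the features bright on 1 array or within 2 grid steps left out, it gave 679 and 451 calls, against the 590. Runs of neighbours with smaller differences, such as features 64 to 73, stayed in, so these counts may still hold local effects. With array means 0 features were called. That fit balances the dyes of each array where both have a value and rests on 2 values per side, so its count says little about the 404. Given the calls from the other pairings, the 404 calls cannot be taken as a side difference, though one in some of these features is not excluded.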

How the results depend on the processing

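No feature passed an adjusted p of 0.05 under the replicate block (0 calls), without the array block, with array means, in either dye alone, under quantile normalisation or median centring, with the filters on dim or incomplete features, with an intensity trend or robust moderation, or at a threshold of 0.10. The exceptions were 404 calls without the dye term, 763 features with an unadjusted p under 0.05 and at least 1.5-fold, and 0 to 52 calls when 1 sample was left out, all from the 4 fits without a Cy3 sample (10, 52, 31 and 25). Of the 118 calls in those 4 fits, 110 lay within 2 grid steps of a feature bright on 1 array, as did 15.4% of the tested features; the cause was not tested. The 1194 features at an unadjusted p under 0.05 became 2134 with the replicate block, 1811 without the array block, 2803 without the dye term, 655 in Cy3 alone, 469 in Cy5 alone, 512 with the features below the median level left out (fewer features tested), and 809 to 2122 with 1 sample left out, the highest without left replicate 4; the cause was not tested for the others. The share of them higher in left was 40.9%, and 54.3% after quantile normalisation, 65.7% after median centring, 75.4% in Cy3 alone and 20% in Cy5 alone. With 1 sample left out it was 27.3% to 55.5%. The dye difference of 26966 features fell to 0 under quantile normalisation, and was 26549 to 27110 with 1 sample left out. The median difference ranged from -0.161 to 0.0231 over 23 alternatives, and from -0.11 to 0.00464 with 1 sample left out; each alternative moved it by less than the SD of 0.135 between sample medians within side and dye. The replicate numbers did not meet the criterion for pairing, a correlation over 0.1 in every pair: after side and dye were removed, same-numbered left and right samples correlated at -0.093, 0.00133, -0.166 and 0.261, where independent samples give -0.2 and pairing is not excluded, against 0.328 to 0.599 for samples sharing an array. The 8 samples could be split into groups of 4 and fitted with the dye term in 34 ways. Of these, 14, the real one among them, gave at least the 1194 features at an unadjusted p under 0.05 in the limma test, with up to 3192. Chance is thus not excluded for that count. Most splits break up arrays, which side does not, and the others that kept arrays whole gave 1357 and 1163, too few for a test. For the count of 0 calls the splits decide nothing, as all 34 must give at least 0; the highest other split gave 30. The list tests and the test on 1 value per gene were not run, for want of gene names. In the simulation 27.3% of 2-fold changes were called.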

Other observations

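The 15224 features measured in all 4 Cy3 samples but too rarely in Cy5 to be tested were compared by side with limma. Of these, 0 passed an adjusted p of 0.05 over 2 samples per side, and 119 had an unadjusted p under 0.05.

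Estimates of at least 2-fold numbered 585 for left against right arrays, 582 for the arrays of replicates 1 and 2 against those of 3 and 4, and 583 for the remaining pairing, over the 24017 features measured in all samples. The differences measured in Cy3 and in Cy5 correlated across features at 0.698, 0.537 and 0.642 in the same order. A spot that is bright in both dyes of 1 array enters all 3 counts and all 3 correlations. With the features bright on 1 array and those within 2 grid steps left out, 20503 features remained, the counts were 171, 162 and 159, and the correlations were 0.522, 0.307 and 0.393. These 3 pairings are too few for a test.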
